A study of Mus musculus with 10 samples.

How the data were processed

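RNA was measured on 10 single-colour Affymetrix-type expression arrays, 2 for each of 5 groups of sorted mouse leukaemia cells. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 6 µg of it. Per the labels, the 2 arrays of a group are biological replicates. The groups were taken from the sample titles, and the labels do not spell out the subset names SC, PD and TD.

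The values used were the deposited table of 45037 probe sets on 10 arrays. Per the submitters' processing notes, the authors made these values with MAS5, Affymetrix's summary of a probe set's perfect-match and mismatch probes, and its version is not given in the sources used here. The deposited values are on a log2 scale, as judged from their range and their floor at 0. After returning them to a linear signal, the mean signal without the lowest and highest 2% of probe sets lay between 496.3 and 497 on every array, near a scaling target of 500. Such scaling fixes one trimmed mean per array and leaves the rest of the distribution free. The 75th percentile of log2 signal ran from 8.28 (UNPD replicate 1) to 8.78 (UNTD replicate 2). Between 0.908% and 2.03% of probe sets per array stood at the floor. No detection call accompanied the values, so a level at or below an array's 40th percentile (4.81 to 5.12 on the log2 scale) is called the dim-signal level below. For a gene at or under that level on both arrays of a group, a fold is given as at least N-fold, computed from the other group's mean against the dim group's mean of that level, and the adjusted p is that of the fit. The number of arrays limits the precision of every value.

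Probe sets were named through the platform annotation given with the data. Of 45037 probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none. A total of 34741 probe sets matched a gene identifier in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names and for gene length. No genome build accompanied the values, and no coordinates are given. A probe set was kept when its signal was above its array's 40th percentile on at least 2 arrays, which left 32686 (72.6%). Of the kept probe sets with exactly 1 symbol, the one with the highest mean log2 signal stood for the gene, giving 14581 genes tested. For 6756 of them a choice between several probe sets was made.

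Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on the log2 values, with the deposited scaling kept and no pseudocount. All 10 arrays entered 1 fit with 5 group means, which left 5 residual degrees of freedom and a prior of 6.57. The fit takes a gene's spread as equal in the 5 groups. Over bright genes the SD between replicates was 0.467 for RATD and 0.503 for RAPD against 0.158 for UNSC. The SE of a contrast with RATD or RAPD may therefore be too small. There were 6 comparisons between groups and 1 interaction, the ATRA difference in the TD subset minus that in the PD subset. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 14581 genes within a contrast, and a gene was called at an adjusted p under 0.05. A difference is written as log2 ± SE of the fit, and a level as mean log2 signal ± SD of 2 arrays. A difference of log2 values of dim genes is uncertain because MAS5 values near the floor spread widely.

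A set of 26 gene lists (723 symbols) covering granule proteins, neutrophil functions, transcription factors, other blood and marrow cell types, and cell states was written from general knowledge before the data were examined. Each list was tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg over the 26 lists of a contrast. With a correlation estimated from these arrays, camera called 0 lists in each of the 7 contrasts, and that adjusted p is given beside the result of each called list. Each called list is also described by how many members passed the gene-level test over all genes and over the list alone. List medians carry bootstrap 95% intervals over the members, which are not independent of each other. The genes named follow a rule fixed in advance, and not all genes that it gives are printed: in each contrast the 6 called genes with the largest difference in each direction among those whose arrays do not overlap and that have a full symbol, the 3 members of smallest p of each called list, up to 3 members of smallest p of other lists, 10 granulocyte anchor genes, and in the ATRA contrasts 6 retinoid-related genes, where measured. The anchor genes Ly6g and Cebpe and the retinoid-related gene Cd38 were not among the genes tested. With 2 arrays against 2, chance alone gives non-overlapping values for 33.3% of genes.

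The fit was tested on simulated arrays with 200 of 14581 genes changed. For UNPD against UNSC it recovered 26.0% of genes changed 2-fold and 72.4% of those changed 8-fold, with 5.26% false calls. For RATD against UNTD it recovered 23.3% of the 2-fold and 74.8% of the 8-fold changes, and for the interaction 4.18% and 50.6%. For RAPD against UNPD, camera called a secondary granule list shifted by 1 log2 unit in 20 of 20 runs. The simulated noise was independent between genes, while the correlation estimated on the real arrays for that list was 0.431. The simulations therefore do not show how the calls behave with correlated genes or with differences shared across a whole array.

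Alternatives chosen before the data were examined were quantile normalization, scaling to a common 75th percentile, pseudocounts of 3.05 and 48.8, no dim filter or one at the 60th percentile, eBayes without the trend, a fit of only the arrays compared, the replicate number as a block, the mean of a gene's probe sets, all probe sets, array weights, an added 2-fold limit, and leaving out each array. A pseudocount of 12.2 and the array's 75th percentile as a covariate were added after seeing the data. Where leaving out an array left a group with 1 array, the lone array was assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.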

Results

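Gene expression was profiled in bone marrow cells of a mouse model of acute promyelocytic leukaemia (APL), a myeloid leukaemia driven by the fusion of PML with the retinoic acid receptor RARα that blocks cells at the promyelocyte stage. Leukaemic cells of FVB N/J mice carried GFP from a retrovirus, were expanded by transplantation into syngeneic recipients, and were sorted by flow cytometry into subsets called SC, PD and TD. Untreated marrow gave the groups UNSC, UNPD and UNTD. Marrow of recipients given all-trans retinoic acid (ATRA), a ligand of RARα used to differentiate APL cells, gave RAPD and RATD. The dose was 10 mg/kg, and its duration is stated as 5 days in the treatment protocol but as 3 to 5 days in the source names. Each group had 2 arrays, and 14581 genes were tested.

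The arrays were first compared over the 6329 genes with a mean log2 signal of at least 9. The SD of the log2 difference between the 2 arrays of a group was 0.158 for UNSC, 0.256 for UNTD, 0.305 for UNPD, 0.467 for RATD and 0.503 for RAPD. The first principal component held 59.2% of the variance and had the UNPD arrays at 55.8 and 40.8 and RAPD replicate 2 at 33.6, while RAPD replicate 1 lay at -0.226 and every other array below it. These 3 arrays also had the lowest 75th percentiles of log2 signal (8.28, 8.35 and 8.41, against 8.60 to 8.78 on the others). RATD replicate 1 lay nearer to the UNTD arrays (SD 0.312 and 0.309) than to RATD replicate 2 (0.467). RATD replicate 2 and RAPD replicate 1 lay nearer to each other (0.45) than either did to the other array of its own group.

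**Figure D1:**
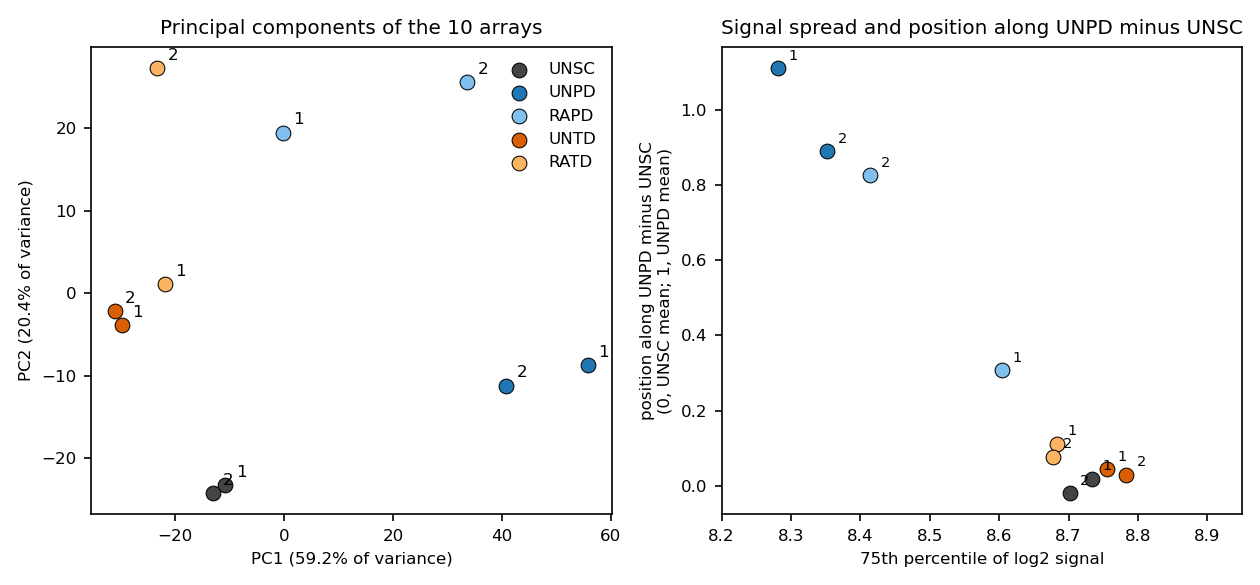
Left, the 10 arrays on the first 2 principal components, with the replicate number beside each point and colours for the 5 groups. Right, each array's 75th percentile of log2 signal against its position along the UNPD minus UNSC difference of bright genes, an axis that the UNSC and UNPD arrays themselves define (0 is the UNSC mean, 1 the UNPD mean). RAPD replicate 2 lies at 0.825 and RAPD replicate 1 at 0.308.

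To describe how the untreated subsets differ, UNPD was first compared with UNSC. Some secondary granule genes were higher in UNPD: Ltf, which encodes lactoferrin, by 2.87 ± 0.48 log2 units (11.06 ± 0.44 against 8.19 ± 0.10, adjusted p = 0.0021), Ngp, another granule protein, by 1.88 ± 0.24, and Lcn2, a siderophore-binding granule protein, by 1.18 ± 0.18. Camp, another gene of these granules, was called higher as well. Among the genes with the largest decreases, Ptgs2, the inducible cyclooxygenase, was at least 12.8-fold lower, Il1r1, the interleukin-1 receptor, at least 8.50-fold lower, and Sectm1a was lower by 4.93 ± 0.60, with only 1 of the 2 UNPD arrays above the dim-signal level. The progenitor gene Kit (log2 difference -0.28 ± 0.20, adjusted p = 0.34), the primary granule genes Mpo (0.19 ± 0.27) and Elane (0.62 ± 0.22, adjusted p = 0.063), and Myc (0.07 ± 0.21) did not pass the test.

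Of 23 measured secondary and tertiary granule genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.0152, adjusted p = 0.865 with an estimated correlation). The other granulocyte lists were not called: of 25 mature neutrophil genes 4 rose and 2 fell (adjusted p = 0.575), of 17 primary granule genes 0 rose and 1 fell (0.302), and of 18 granulocyte transcription factor genes 5 rose and 1 fell (0.358). Of 16 respiratory burst and phagocytosis genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.853 with an estimated correlation). Among them were the integrin gene Itgb2 (1.57 ± 0.23), the kinase gene Fgr (1.16 ± 0.19) and Cyba, a subunit of the phagocyte oxidase (0.89 ± 0.17). Of 39 oxidative phosphorylation genes, 28 rose and 2 fell (31 and 2 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 5.3e-06, adjusted p = 0.865 with an estimated correlation). Uqcrq, a subunit of respiratory complex III, rose by 0.97 ± 0.16. Beside these groups, the difference fell with gene length: its Spearman correlation across genes was -0.26, and -0.474 among bright genes, where genes are not independent replicates. Among the 51 cell cycle genes, a list that was not called (adjusted p = 0.945), 15 rose and 14 fell: the mitotic genes Cenpe and Cenpf were lower by 2.10 ± 0.28 and 2.23 ± 0.32, and Ube2c was higher by 1.12 ± 0.18. Of the lists for other cell types, erythroid genes had a median of 0.72 (6 higher, 1 lower, adjusted p = 0.124), and Slc4a1, the red cell anion exchanger, was at least 3.26-fold higher.

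In all, 3766 of 14581 genes were called in UNPD against UNSC, 1551 higher and 2215 lower. The median gene differed by 0.20 (0.31 after quantile normalization and 0.60 after scaling to a common 75th percentile). The share of higher calls was 41.2%, 54.0% and 72.9% under these 3 scalings. After quantile normalization none of the lists was called (adjusted p = 0.417 for granule, 0.129 for respiratory burst and 0.417 for oxidative phosphorylation genes). The granule and respiratory burst medians stayed near their values (0.75 against 0.83, and 0.67 under both), while the oxidative phosphorylation median was 0.20. Without UNPD replicate 1, UNSC replicate 1 or UNSC replicate 2 the count was 1191, 1818 or 1518, and the granule and respiratory burst lists were not called without UNPD replicate 2 (adjusted p = 0.117 and 0.0912). With the 75th percentile as a covariate limma called 0 genes, with 431 at an unadjusted p under 0.05.

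UNTD was next compared with UNSC. Genes of monocytes and macrophages were far higher in UNTD: Irf8, a transcription factor of the monocyte and dendritic lineage, by 6.18 ± 0.44 log2 units (11.96 ± 0.45 against 5.78 ± 0.39, adjusted p = 1.1e-05), Ctss, a lysosomal protease, by 4.89 ± 0.33, and Apoe by 4.66 ± 0.35. Trem2, a receptor of macrophages and microglia, was at least 58.3-fold higher. Fpr2, a receptor for formyl peptides on mature phagocytes, was higher by 5.70 ± 0.21. Kit (by 1.87 ± 0.20 on the log2 scale), Elane (by 1.34 ± 0.22), Mpo (by 1.14 ± 0.27) and Nkg7 (by 3.24 ± 0.36) all fell.

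Of 25 monocyte and dendritic genes, 17 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 2.77 (95% interval 1.47 to 3.73, camera adjusted p = 9.24e-16, adjusted p = 0.0775 with an estimated correlation). Of 18 macrophage genes 6 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 6.12e-06, adjusted p = 0.0614 with an estimated correlation), and Msr1, a scavenger receptor, rose by 5.13 ± 0.41. Of 16 respiratory burst genes 11 rose and 0 fell (13 and 0 over the list alone, camera adjusted p = 1.91e-11, adjusted p = 0.0672 with an estimated correlation). Fgr was higher by 3.88 ± 0.19 and Lsp1, an actin-binding protein of leukocytes, by 4.11 ± 0.38. Of 25 mature neutrophil genes 8 rose and 0 fell (10 and 0 over the list alone), with Ifitm6 at 4.01 ± 0.21 (camera adjusted p = 4.92e-08, adjusted p = 0.0614 with an estimated correlation). Of 23 secondary and tertiary granule genes 11 rose and 0 fell (13 and 0 over the list alone), with Ltf at 2.45 ± 0.48 (camera adjusted p = 1.74e-08, adjusted p = 0.235 with an estimated correlation). Of 29 immediate early genes, induced within minutes of a stimulus, 12 rose and 0 fell (17 and 1 over the list alone, camera adjusted p = 1.64e-09, adjusted p = 0.0614 with an estimated correlation). Klf4 rose by 3.73 ± 0.31 and Nr4a1 by 2.90 ± 0.28. Klf4 and Klf2 are also on the monocyte and dendritic list, so these lists are not independent. The 27 retinoid response genes held 6 that rose and 0 that fell (14 and 0 over the list alone, camera adjusted p = 4.41e-06, adjusted p = 0.0614 with an estimated correlation). Among them, in cells that had received no ATRA, were Dhrs3, a retinaldehyde reductase, at 2.36 ± 0.23 and the receptor gene Rarg at 2.16 ± 0.26. Cyp26a1, a gene induced by retinoids, overlapped between the groups (5.34 and 3.02 in UNTD, 2.53 and 5.42 in UNSC). The list shares Btg2 with the immediate early list, Icam1 with the antigen presentation list, and Cdkn1a and Tnfsf10 with the apoptosis list.

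Proliferation genes were lower in UNTD. Of 51 cell cycle genes, 0 rose and 12 fell (0 and 31 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 4.43e-12, adjusted p = 0.0775 with an estimated correlation). Nek2 lay at -1.14 ± 0.20 and Tk1, thymidine kinase, at -1.03 ± 0.20. Of 40 genes of MYC and ribosome biogenesis 0 rose and 6 fell (0 and 13 over the list alone), with Nolc1 at -0.84 ± 0.19 (camera adjusted p = 5.49e-07, adjusted p = 0.347 with an estimated correlation). Of 17 primary granule genes 2 rose and 5 fell, also over the list alone (camera adjusted p = 0.0158, adjusted p = 0.349 with an estimated correlation), a call lost without UNTD replicate 2 (adjusted p = 0.134). Of 18 granulocyte transcription factor genes 6 rose and 1 fell, also over the list alone (camera adjusted p = 0.0195, adjusted p = 0.312 with an estimated correlation), a call lost without UNSC replicate 1 or either RATD array (adjusted p = 0.058, 0.0759 and 0.0759). The granulocyte transcription factor list had a median of 0.20 and a mean of 0.61. It holds Irf8, which is also on the monocyte and dendritic list, and Klf6 and Junb, which are also on the immediate early list. The megakaryocyte list was called with 0 of 14 members called, also over the list alone (median 0.71, or 0.44 after quantile normalization, camera adjusted p = 0.0122, adjusted p = 0.108 with an estimated correlation). The oxidative phosphorylation list, with 0 of 39 members higher and 1 lower (0 and 0 over the list alone), was called lower (median -0.21, 0.00226 and 0.499). The glycolysis list, with 4 of 32 higher and 0 lower (5 and 1 over the list alone), was called higher (median 0.25, 0.019 and 0.319). Both were not called without UNTD replicate 2 (adjusted p = 0.0724 and 0.0649). Of other cell types, the B cell (median -0.20, adjusted p = 0.867), T and NK cell (0.25, 0.706), erythroid (0.08, 0.29) and eosinophil, basophil and mast cell lists (-0.38, 0.0549) were not called. In all 1189 genes were called, 723 higher and 466 lower, and the median gene differed by -0.04. The count was 442, 398, 494 or 449 without UNSC replicate 1, UNSC replicate 2, UNTD replicate 1 or UNTD replicate 2, 571 without the eBayes trend, 2924 with array weights and 3291 when only these 4 arrays were fitted.

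UNTD against UNPD gave the most calls, with the same cell-type genes in front. Irf8 was higher by 5.66 ± 0.44, Ctss by 5.04 ± 0.33, Clec7a, a receptor for fungal glucans, by 5.11 ± 0.38, and Fpr2 by 5.46 ± 0.21. Trem2 was at least 56.4-fold and Ptgs2 at least 22.2-fold higher. Lpl, lipoprotein lipase, stood at 12.71 ± 0.25 in UNTD and at 5.76 and 2.13 on the UNPD arrays, of which only 1 lay above the dim-signal level, so no size is given (adjusted p = 8.8e-05). Lower in UNTD were Nkg7 (-3.72 ± 0.36), Hdc, histidine decarboxylase (-2.81 ± 0.31), Elane (-1.96 ± 0.22) and Kit (-1.60 ± 0.20), and Atp8a2, a phospholipid flippase, was at least 6.54-fold lower. The secondary granule gene Camp was called lower too, while Ltf (-0.42 ± 0.48, adjusted p = 0.55) and Myc (-0.33 ± 0.21, adjusted p = 0.25) did not pass the test.

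Of 25 monocyte and dendritic genes 15 rose and 0 fell (18 and 0 adjusted over the list alone, median 2.09, camera adjusted p = 1.31e-07, adjusted p = 0.381 with an estimated correlation). Of 29 immediate early genes 16 rose and 1 fell, also over the list alone, with Zfp36, an mRNA decay factor, at 2.73 ± 0.19 (camera adjusted p = 1.7e-06, adjusted p = 0.333 with an estimated correlation). Of 34 interferon response genes 17 rose and 3 fell (17 and 4 over the list alone, camera adjusted p = 0.00434, adjusted p = 0.595 with an estimated correlation). Parp14 rose by 2.79 ± 0.32 and the RNA sensor gene Ifih1 by 1.55 ± 0.23. Of 51 cell cycle genes 7 rose and 29 fell (8 and 30 over the list alone), with Cdk1, the mitotic kinase, at -1.68 ± 0.16 (camera adjusted p = 0.00141, adjusted p = 0.445 with an estimated correlation). Of 39 oxidative phosphorylation genes 2 rose and 34 fell (2 and 35 over the list alone), with a median of -0.75, or -0.48 after quantile normalization (camera adjusted p = 1.96e-08, adjusted p = 0.445 with an estimated correlation). The lists of mature neutrophil (median 0.49, 9 higher and 1 lower of 25, also over the list alone, camera adjusted p = 0.00194, adjusted p = 0.333 with an estimated correlation), macrophage (2.41, 10 and 1 of 18, also over the list alone, 0.00163 and 0.333) and respiratory burst genes (0.77, 6 and 0 of 16, or 7 and 1 over the list alone, 0.00918 and 0.445) were called higher. That of MYC and ribosome biogenesis was called lower (-0.68, 7 and 21 of 40, or 9 and 22 over the list alone, 0.00552 and 0.677), but not after quantile normalization (adjusted p = 0.141), where its median was -0.68 as well. The difference correlated with gene length across genes (Spearman 0.246, and 0.447 among bright genes). In all 5144 genes were called, 2630 higher and 2514 lower. The median gene differed by -0.13 (-0.33 after quantile and -0.58 after 75th percentile scaling), and 51.1%, 39.5% and 27.7% of calls were higher. The count was 2982 without UNPD replicate 1, and limma called 0 genes with the 75th percentile as a covariate, where 771 had an unadjusted p under 0.05.

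**Figure D2:**
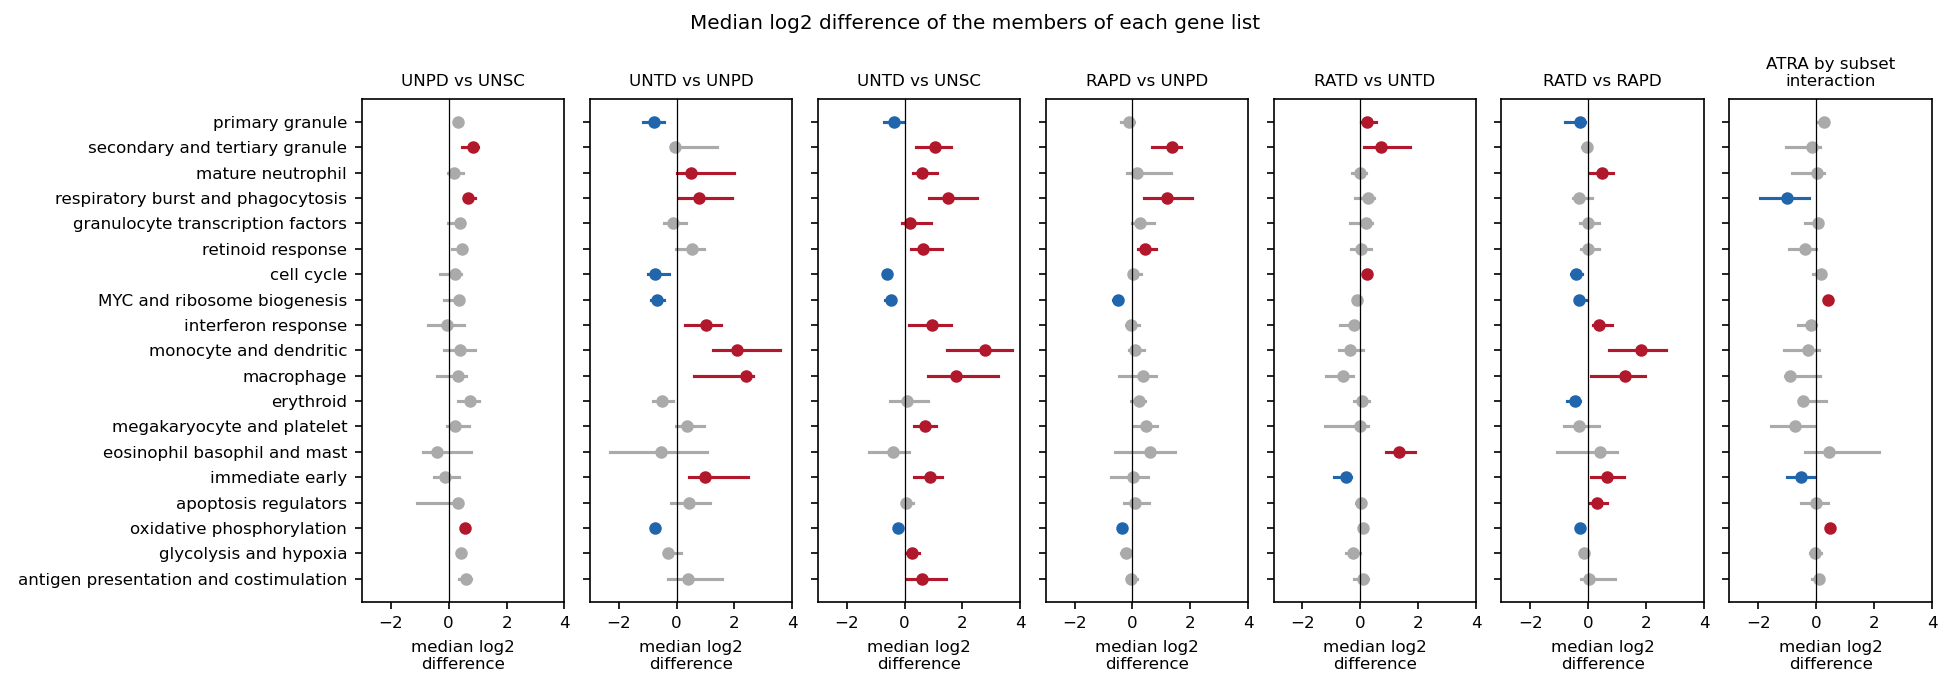
Median log2 difference (points) and bootstrap 95% interval over the members (lines) of the gene lists that camera called in at least 1 contrast, with 1 panel per contrast. Red marks lists called higher, blue lists called lower and grey lists not called. The monocyte and dendritic list lies at 2.77 in UNTD against UNSC and at 0.39 in UNPD against UNSC, where it was not called.

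The response of the PD subset to ATRA was examined by comparing RAPD with UNPD. Genes of the late granules of neutrophils rose: Mmp9, the gelatinase of tertiary granules, by 6.22 ± 0.55 log2 units (12.86 ± 0.09 against 6.64 ± 0.71, adjusted p = 0.0003), Ltf by 3.76 ± 0.48 and Cybb, the catalytic subunit of the phagocyte oxidase, by 2.57 ± 0.23. The immunoglobulin receptor gene Fcgr4 rose by 4.07 ± 0.35 and Fpr2 by 4.31 ± 0.21. Of genes known to respond to retinoids, Cyp26a1, which degrades retinoic acid, was at least 7.56-fold higher and Dhrs3 was higher by 1.93 ± 0.23. Ifitm1 (-5.14 ± 0.64), Clec4d (-3.95 ± 0.69), Jun (-2.49 ± 0.32) and Fos (-1.67 ± 0.28) were lower, and Calhm6 was at least 5.02-fold lower. The immediate early list, which holds Jun and Fos, was not called, with 4 of 29 members higher and 6 lower (median 0.03, adjusted p = 0.992). Nor was the mature neutrophil list, which holds Ifitm1 and Clec4d, with 8 of 25 members higher and 5 lower (median 0.16, adjusted p = 0.201). Kit (-0.52 ± 0.20, adjusted p = 0.11), Mpo (-0.42 ± 0.27), Elane (0.03 ± 0.22), Camp (0.08 ± 0.20) and Myc (-0.24 ± 0.21) did not pass the test, nor did Rara (1.97 ± 0.66, adjusted p = 0.082, with 1 of the 2 UNPD arrays above the dim-signal level) or Pml (0.69 ± 0.34, adjusted p = 0.21), the genes whose products form the fusion.

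Of 23 secondary and tertiary granule genes 12 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 1.35 (95% interval 0.69 to 1.69, camera adjusted p = 9.29e-08, adjusted p = 0.611 with an estimated correlation). Of 16 respiratory burst and phagocytosis genes 9 rose and 0 fell (10 and 0 over the list alone, median 1.21, camera adjusted p = 9.8e-08, adjusted p = 0.358 with an estimated correlation). Of 27 retinoid response genes 4 rose and 1 fell, also over the list alone, with Dhrs3 among them (median 0.43, or 0.27 after quantile normalization, camera adjusted p = 0.0318, adjusted p = 0.358 with an estimated correlation), a call lost without UNPD replicate 2 or RAPD replicate 2 (adjusted p = 0.0568 and 0.354). Of 40 MYC and ribosome biogenesis genes 0 rose and 6 fell (1 and 21 over the list alone), with Cad, an enzyme of pyrimidine synthesis, at -1.03 ± 0.23 (camera adjusted p = 9.81e-05, adjusted p = 0.611 with an estimated correlation). Of 39 oxidative phosphorylation genes 0 rose and 3 fell (0 and 12 over the list alone), with Ndufa5 at -0.97 ± 0.16 (camera adjusted p = 1.02e-06, adjusted p = 0.611 with an estimated correlation). The difference correlated with gene length (Spearman 0.193, and 0.383 among bright genes). The cell cycle (median 0.02, adjusted p = 0.909) and monocyte and dendritic lists (0.09, 0.515) were not called.

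In all 1173 genes were called in RAPD against UNPD, 708 higher and 465 lower. The share of higher calls was 60.4%, against 55.7% after quantile and 34.8% after 75th percentile scaling, which gave 1842 calls and moved the median of all genes from -0.01 to -0.20. The count moved by over 1.5 times with the removal of any array, those of other groups included. It was 74 or 289 without UNPD replicate 1 or 2, 124 or 2556 without RAPD replicate 1 or 2, 475 or 477 without UNSC replicate 1 or 2, 542 or 526 without UNTD replicate 1 or 2, and 1999 or 2010 without RATD replicate 1 or 2. It was 29 without the eBayes trend and 15 with the 75th percentile as a covariate.

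For the TD subset, RATD was compared with UNTD. Genes of secondary granules rose here too: Ltf by 3.59 ± 0.48 log2 units (14.23 ± 1.10 against 10.65 ± 0.90, adjusted p = 0.014), Pglyrp1, a peptidoglycan-binding granule protein, by 3.23 ± 0.50 and Olfm4 by 1.32 ± 0.21. The glucose transporter gene Slc2a3 rose by 3.75 ± 0.45 and Hdc by 2.60 ± 0.31, and Atp8a2 was at least 2.68-fold higher. Lower were Cx3cr1, the fractalkine receptor of monocytes (-3.13 ± 0.47), the chemokine gene Ccl3 (-2.37 ± 0.32), the signalling regulators Rgs1 (-3.29 ± 0.54) and Dusp1 (-2.28 ± 0.26), and the serotonin transporter gene Slc6a4 (-3.48 ± 0.43). Cyp26a1 stood at 9.07 and 8.26 on the RATD arrays against 5.34 and 3.02 on the UNTD arrays, a difference of 4.48 ± 0.91 that did not pass the test (adjusted p = 0.074). Kit (0.14 ± 0.20), Mpo (-0.16 ± 0.27), Itgam (0.03 ± 0.26) and Dhrs3 (-0.43 ± 0.23) did not pass it either.

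Of 23 secondary and tertiary granule genes 4 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 1.02e-07, adjusted p = 0.651 with an estimated correlation). Of 13 eosinophil, basophil and mast cell genes 1 rose and 0 fell (5 and 0 over the list alone), with a median of 1.35, Hdc being the gene called, and Siglecf at 1.35 ± 0.27 (adjusted p = 0.074) (camera adjusted p = 2.98e-06, adjusted p = 0.133 with an estimated correlation). Of 29 immediate early genes 0 rose and 1 fell (1 and 11 over the list alone), with Jun at -1.56 ± 0.32 (adjusted p = 0.074) beside Dusp1 (camera adjusted p = 2.55e-08, adjusted p = 0.133 with an estimated correlation). The cell cycle list had a median of 0.23 with 0 of 51 members called, also over the list alone (camera adjusted p = 0.000235, adjusted p = 0.651 with an estimated correlation), and was not called without UNTD replicate 1 or RATD replicate 1 (adjusted p = 0.136 and 0.137). The primary granule list, with 1 of 17 members called higher and 0 lower (5 and 1 over the list alone), had a median of 0.24, and the member called was again Hdc, which is on both lists (camera adjusted p = 0.00789, adjusted p = 0.833 with an estimated correlation). It was not called without UNTD replicate 2 or RATD replicate 1 or after quantile normalization (adjusted p = 0.432, 0.0754 and 0.0987), and its median after quantile normalization was 0.14. The retinoid response list was not called, with 0 of 27 members higher and 0 lower (1 and 0 over the list alone, median 0.03, camera adjusted p = 0.975). In all 42 genes were called, 28 higher and 14 lower. The count was 856 without RATD replicate 1 and 16 without RATD replicate 2. It was 6 or 1 without UNTD replicate 1 or 2, 10 without UNSC replicate 1 or 2, 16 or 18 without UNPD replicate 1 or 2, and 24 without RAPD replicate 1 or 2. It was 1 without the eBayes trend, 2 with the covariate, 25 without the dim filter, 97 with a pseudocount of 48.8, 115 with 75th percentile scaling, and limma called 0 when only these 4 arrays were fitted.

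**Figure D3:**
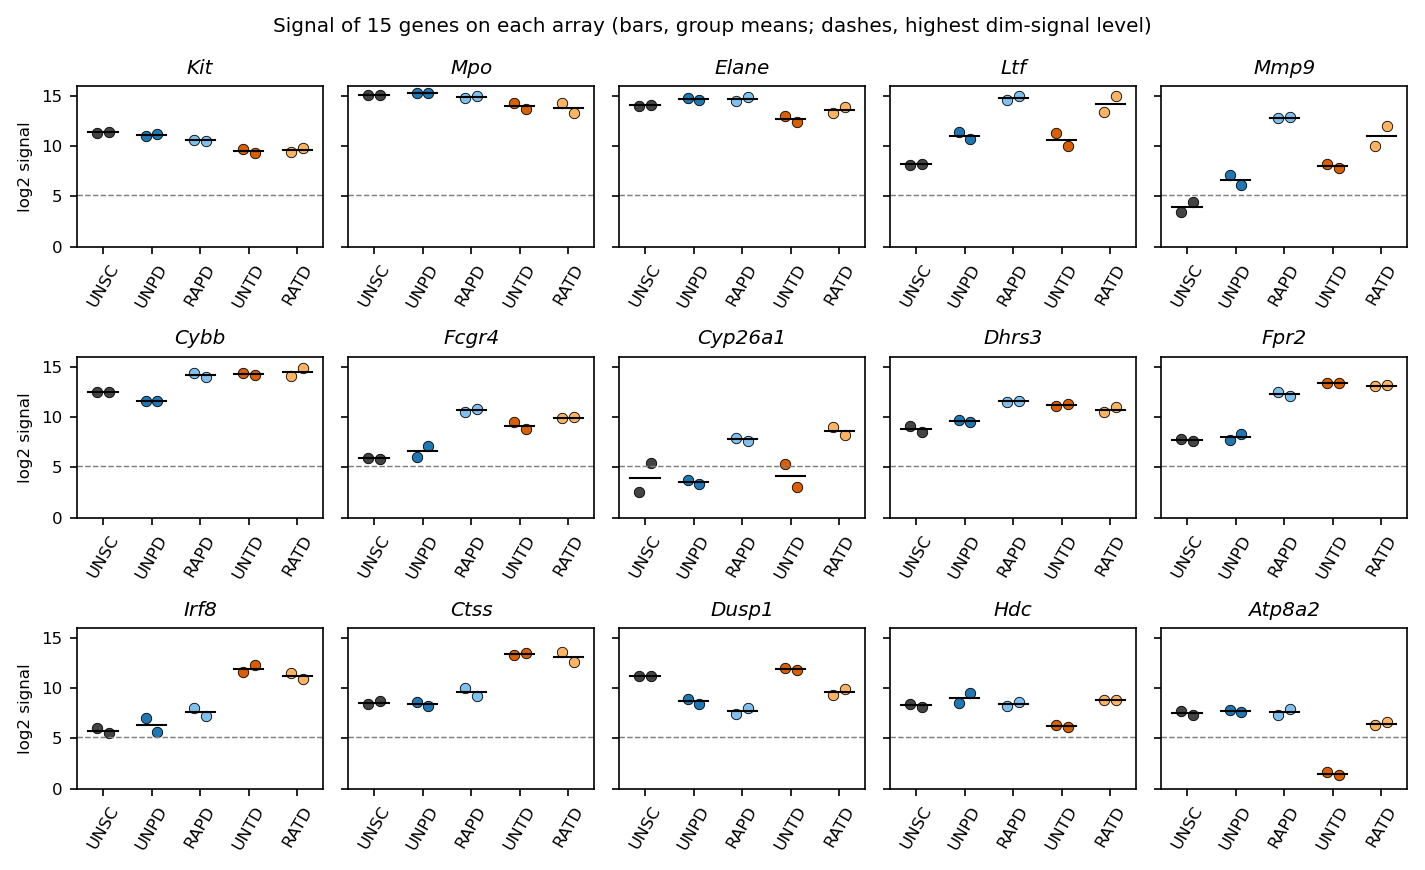
Log2 signal of 15 genes on each of the 10 arrays (points), with group means (bars) and the highest dim-signal level of the arrays (dashes, 5.12). Ltf reached 14.82 in RAPD and 14.23 in RATD from 11.06 in UNPD and 10.65 in UNTD, while Fpr2 stood at 13.45 in UNTD before treatment.

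After ATRA, the subsets were compared with each other as RATD against RAPD. These groups are not cleanly apart, since RATD replicate 2 lay nearer to RAPD replicate 1 (SD 0.45 over bright genes) than to RATD replicate 1 (0.467). Monocyte and macrophage genes were higher in RATD: Ctss by 3.45 ± 0.33 log2 units, Msr1 by 4.09 ± 0.41 and Irf8 by 3.61 ± 0.44, and Arg1, arginase, was at least 35.7-fold higher (adjusted p = 0.00053). The immediate early gene Jun was higher by 3.39 ± 0.32. Lower in RATD were Igll1, a component of the pre-B-cell receptor (-3.05 ± 0.21), Tk1 (-1.70 ± 0.20), Uhrf1, which maintains DNA methylation (-1.31 ± 0.18), Elane (-1.11 ± 0.22) and Kit (-0.94 ± 0.20). Ltf (-0.59 ± 0.48), Camp (0.00 ± 0.20), Itgam (-0.04 ± 0.26) and Cyp26a1 (0.87 ± 0.91) did not pass the test.

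Of 25 monocyte and dendritic genes 12 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.81, camera adjusted p = 4.73e-11, adjusted p = 0.168 with an estimated correlation). Of 18 macrophage genes 5 rose and 0 fell (7 and 0 over the list alone, camera adjusted p = 0.00127, adjusted p = 0.168 with an estimated correlation). Of 29 immediate early genes 9 rose and 0 fell (14 and 1 over the list alone, camera adjusted p = 5.09e-06, adjusted p = 0.168 with an estimated correlation). Of 51 cell cycle genes 2 rose and 14 fell (4 and 23 over the list alone, median -0.43, camera adjusted p = 7.53e-05, adjusted p = 0.348 with an estimated correlation). The mature neutrophil list was called higher (median 0.47, 6 higher and 0 lower of 25, or 9 and 1 over the list alone, camera adjusted p = 0.00127, adjusted p = 0.168 with an estimated correlation), but not without RAPD replicate 1 (adjusted p = 0.0606). The interferon (median 0.36, or 0.21 after quantile normalization, 0 of 34 members called, also over the list alone, camera adjusted p = 0.00872, adjusted p = 0.825 with an estimated correlation) and apoptosis lists (0.29, 1 higher and 0 lower of 30, or 5 and 0 over the list alone, 0.0182 and 0.168) were called higher. Called lower were the erythroid list (-0.47, 0 of 24 members called, also over the list alone, 0.00872 and 0.168) and that of oxidative phosphorylation (-0.29, 1 higher and 0 lower of 39, also over the list alone, 0.000938 and 0.825). So were those of MYC (-0.31, 0 higher and 1 lower of 40, or 0 and 0 over the list alone, 0.0363 and 0.855) and primary granules (-0.27, 1 higher and 5 lower of 17, or 1 and 8 over the list alone, 0.0345 and 0.801). Each of these 6 lost its call without at least 1 array: interferon without RAPD replicate 1 or RATD replicate 1 (adjusted p = 0.19 and 0.945), apoptosis without RAPD replicate 2 or RATD replicate 1 (0.0773 and 0.0872), erythroid without RATD replicate 1 (0.0658) and oxidative phosphorylation without RAPD replicate 2 (0.0878). MYC lost it without either UNPD array (0.0568 for each), RAPD replicate 1 (0.315) or RATD replicate 2 (0.617, with the opposite direction), and primary granule without either UNPD array (0.0568 for each), RAPD replicate 2 (0.143) or RATD replicate 1 (0.0706). After quantile normalization the oxidative phosphorylation, MYC and primary granule lists were not called (adjusted p = 0.19, 0.171 and 0.305), with medians of -0.20, -0.31 and -0.10, so that of MYC stayed near its value. Without the dim filter the erythroid list was not called (0.106). The difference correlated with gene length (Spearman 0.203, and 0.371 among bright genes). In all 697 genes were called, 387 higher and 310 lower, or 55.5% higher, against 39.2% after 75th percentile scaling, which moved the median of all genes from -0.06 to -0.23. The count was 2453 or 83 without RAPD replicate 1 or 2, 434 without RATD replicate 1, 226 or 227 without UNSC replicate 1 or 2, 391 or 410 without UNPD replicate 1 or 2, and 262 or 254 without UNTD replicate 1 or 2. It was 28 without the eBayes trend, 8 with the covariate, 58 when only these 4 arrays were fitted and 141 with array weights.

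Whether the ATRA difference itself differed between the subsets was tested by the interaction, which called 35 genes, 9 with a higher and 26 with a lower ATRA difference in TD than in PD (25.7% higher, or 28.6% and 51.2% after quantile and 75th percentile scaling, which moved the median of all genes from 0.02 to 0.15 and 0.30). The lower ones held phagocyte genes that were called with ATRA in PD and not in TD. Each side averages 2 unlike treated arrays, with an SD over bright genes of 0.503 between the RAPD and 0.467 between the RATD arrays. Along the ATRA difference of PD, the slope of RATD replicate 1 minus the UNTD mean was -0.00916 and that of RATD replicate 2 was 0.426. Fpr2 rose by 4.31 ± 0.21 in PD and had a difference of -0.29 ± 0.21 in TD (interaction adjusted p = 7.6e-05). The differences in PD and TD were 2.57 ± 0.23 and 0.17 ± 0.23 for Cybb (adjusted p = 0.017), 1.83 ± 0.19 and -0.58 ± 0.19 for Fgr (adjusted p = 0.0046), and 1.93 ± 0.23 and -0.43 ± 0.23 for Dhrs3 (adjusted p = 0.017). In untreated cells these genes were already higher in UNTD than in UNPD, with Fpr2 at 13.45 against 7.99 and Cybb at 14.31 against 11.62. Hdc went the other way, at -0.61 ± 0.31 in PD and 2.60 ± 0.31 in TD (adjusted p = 0.017), as did Phgdh, the first enzyme of serine synthesis, at -2.29 ± 0.26 and 0.11 ± 0.26 (adjusted p = 0.032). Of 16 respiratory burst genes 0 had a higher and 3 a lower ATRA difference in TD (0 and 8 adjusted over the list alone, camera adjusted p = 9.63e-06, adjusted p = 0.409 with an estimated correlation). The ATRA difference of Ltf (-0.17 ± 0.67, adjusted p = 0.93) was not shown to differ between the subsets. The count was 1374 or 9 without RAPD replicate 2 or 1, 175 without RATD replicate 2, 5 or 3 without UNTD replicate 1 or 2, 11 without UNPD replicate 1, and 11 without UNSC replicate 1 or 2. It was 4 without the eBayes trend, 14 without the dim filter, 82 with 75th percentile scaling and 1 with the covariate.

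**Figure D4:**
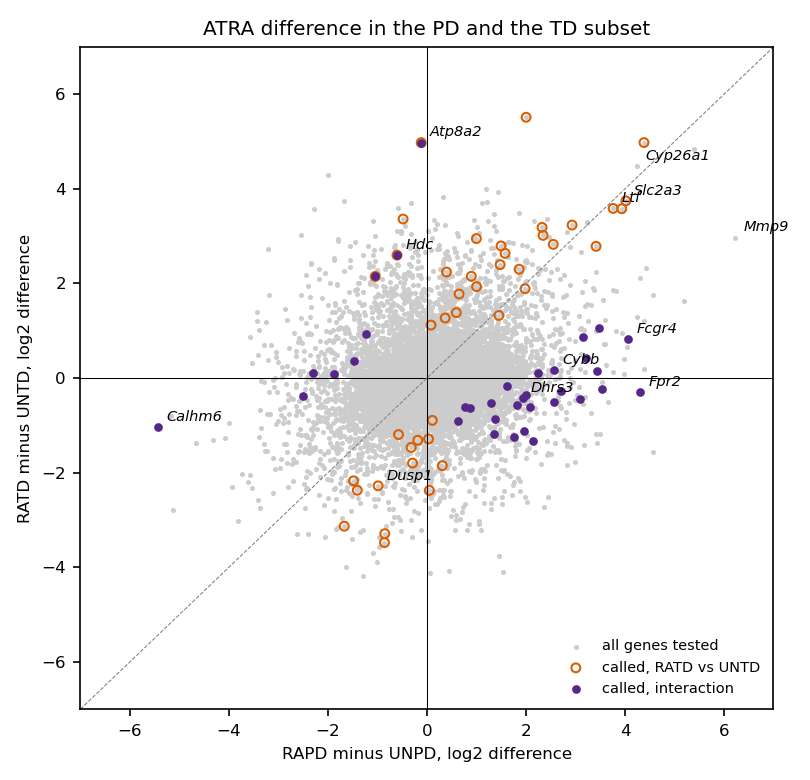
Log2 difference with ATRA in the PD subset (horizontal axis) and in the TD subset (vertical axis) for 14581 genes (grey), with the genes called in RATD against UNTD circled and those called by the interaction filled. The dashed line marks equal differences. Ltf lies near it at 3.76 and 3.59, and Fpr2 away from it at 4.31 and -0.29.

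Comparisons were also set against each other across genes, which are not independent replicates. The ATRA differences of the PD and TD subsets, which share no arrays, had a Pearson correlation of 0.197 over 14581 genes and 0.349 among bright genes. Of their called genes 12 were higher in both and 4 lower in both, against 1.36 and 0.446 for independent lists, and 0 were called in opposite directions, against 1.57. The TD minus PD difference in untreated cells and after ATRA correlated at 0.528, and at 0.850 among bright genes. The RAPD minus UNPD and UNTD minus UNSC differences correlated at 0.0954 (0.272 among bright genes), and RATD minus RAPD with UNPD minus UNSC at -0.338 (-0.720 among bright genes). The UNPD arrays and RAPD replicate 2 lay apart from the others on the first principal component. Both TD minus PD differences also correlated with gene length among bright genes (Spearman 0.447 untreated and 0.371 after ATRA). What those arrays share may thus give part of the 0.850 and the -0.720, which was not tested. UNPD minus UNSC and UNTD minus UNPD share the UNPD arrays and correlated at -0.630 (covariance -0.745), against -0.499 (covariance -0.210) simulated with no effect. RAPD minus UNPD and UNTD minus UNPD share them too and correlated at 0.478 (covariance 0.484), against 0.502 (covariance 0.214) simulated, so part of either value may come from the shared arrays.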

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

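The tests reported here were planned before the data were examined. Whether the ATRA difference of the TD subset differs from that of the PD subset was tested by the interaction in limma, and 35 genes passed it at an adjusted p under 0.05 (3 to 1374 with each array left out in turn, as given by array in the report). Each value below is the ATRA difference in TD minus that in PD on the log2 scale, with n = 2 arrays in each of the 4 groups.

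Genes with a more positive difference in TD were Hdc at 3.20, Aars2 at 3.19, Phgdh at 2.41 and Mcpt8, a basophil protease gene, at 2.17. Genes with a more negative difference in TD were Fpr2 at -4.60, Mfsd6 at -3.76, Hacd4 at -3.53, Trib1, which encodes a pseudokinase, at -3.47, Zfp40 at -3.27, Fcgr4 at -3.25, Klf2 at -3.01, Cybb at -2.41, Fgr at -2.41, Dhrs3 at -2.36 and Zfp36 at -1.54. Of these genes and of Atp8a2 and Calhm6, described below, Atp8a2, Hdc and Aars2 were called with ATRA in TD and not in PD, and Zfp36 in neither. The other 13 were called in PD and not in TD. The sizes for Aars2, Mfsd6, Trib1 and Zfp40 are uncertain, because only 1 of 2 arrays of a group lay above the dim-signal level (UNTD for Aars2, UNPD for the others), and with a pseudocount of 48.8 they were smaller and still called. For Atp8a2 (5.09) and Calhm6 (4.40) the value is no measured size, because both UNTD arrays for Atp8a2 and both RAPD arrays for Calhm6 lay under the dim-signal level. With a pseudocount of 48.8 they were 1.5 and 1.16 and were not called, and against that level Atp8a2 was at least 2.68-fold higher with ATRA in TD.

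Of the 26 gene lists, 4 differed in their ATRA response by camera with the preset correlation. The median member differed by -1.02 for respiratory burst and phagocytosis (0 members with a higher and 3 with a lower difference, or 0 and 8 over the list alone, adjusted p = 0.409 with an estimated correlation), by -0.53 for immediate early genes (-0.31 after quantile normalization, 0 and 2, or 0 and 7 over the list alone, adjusted p = 0.409 with an estimated correlation), by 0.46 for oxidative phosphorylation (0.29 after quantile normalization, 0 of 39 called, or 1 and 0 over the list alone, adjusted p = 0.588 with an estimated correlation) and by 0.39 for MYC and ribosome biogenesis (0 of 40 called, also over the list alone, adjusted p = 0.803 with an estimated correlation). The immediate early list was not called without UNPD replicate 2 or RAPD replicate 2 (adjusted p = 0.0749 and 0.137). The MYC list was not called after quantile normalization (adjusted p = 0.227, median 0.33) or without UNPD replicate 2, RAPD replicate 2, UNTD replicate 2 or RATD replicate 1 (adjusted p = 0.0862, 0.205, 0.145 and 0.737). Beside the oxidative phosphorylation list, the interaction had a Spearman correlation of -0.418 with gene length among bright genes.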

How the results depend on the processing

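Of the alternatives, a pseudocount of 12.2 and the 75th percentile as a covariate were chosen after seeing the data. A count is taken as kept within 1.5 times its value with the deposited scaling, and unless the alternative's construction shows it, the cause of a move was not tested. The 7 counts of called genes were all kept under quantile normalization, pseudocounts of 3.05 and 12.2, and a dim filter at the 60th percentile. Scaling to a common 75th percentile gave 6055 for UNPD against UNSC, 1842 for RAPD against UNPD, 115 for RATD against UNTD, 1121 for RATD against RAPD and 82 for the interaction, and kept the other 2. eBayes without the trend gave 2323 for UNPD against UNSC, 571 for UNTD against UNSC, 29 for RAPD against UNPD, 1 for RATD against UNTD, 28 for RATD against RAPD and 4 for the interaction. A pseudocount of 48.8 gave 97 for RATD against UNTD, and no dim filter gave 25 there and 14 for the interaction. Array weights gave 2924 for UNTD against UNSC and 141 for RATD against RAPD, and the mean of a gene's probe sets gave 464 for the latter. With fewer arrays in the fit, only the arrays compared gave 3291 for UNTD against UNSC, 0 for RATD against UNTD, 58 for RATD against RAPD and 13 for the interaction. Counting probe sets gave 7539 for UNPD against UNSC, 10845 for UNTD against UNPD and 1829 for RAPD against UNPD, and asking also for a 2-fold change gave 2019, 3103 and 764 for these and 457 for RATD against RAPD. With the covariate the counts were 0 for UNPD against UNSC and for UNTD against UNPD (431 and 771 at an unadjusted p under 0.05), 15 for RAPD against UNPD, 2 for RATD against UNTD, 8 for RATD against RAPD and 1 for the interaction. With the replicate number as a block, limma called 781 in RAPD against UNPD, 371 in RATD against RAPD and 20 for the interaction, and the number of lists called moved in none of the 7 contrasts. Whether the numbers pair the arrays is not stated.

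Leaving out each array in turn gave 1191 to 4401 genes for UNPD against UNSC, 2982 to 5587 for UNTD against UNPD, 398 to 1641 for UNTD against UNSC, 74 to 2556 for RAPD against UNPD, 1 to 856 for RATD against UNTD, 83 to 2453 for RATD against RAPD and 3 to 1374 for the interaction. The arrays behind the larger moves are named in the report. The number of lists called went from 1 to 6, 9 to 11, 13 to 17, 4 to 5, 5 to 9, 8 to 12 and 2 to 8 in the same order. With an estimated correlation camera called 0 lists in every contrast, and with quantile normalization 0 in UNPD against UNSC.

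Of 358 values of single genes examined, 341 kept direction and side of the threshold under quantile normalization, 254 without the trend and 161 with the covariate. A call that reversed did so in 8 cases. With the covariate, Zfp329 went to 1.71 and Camp to -0.24 in UNPD against UNSC, and Spz1 to 0.11, Bmi1 to -0.46 and Camp to 0.45 in UNTD against UNPD. With the mean of the probe sets, Ndufb8 went to -0.10 in UNPD against UNSC, and Nme1 to 0.33 in UNTD against UNPD and 0.0675 in RATD against RAPD, which shows probe sets of 1 gene that disagree.

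Correlations between comparisons that share no arrays depended on dim genes. Without the dim filter, those of the 2 ATRA differences, of TD minus PD before and after ATRA, of RAPD minus UNPD with UNTD minus UNSC, and of RATD minus RAPD with UNPD minus UNSC were 0.126, 0.389, 0.0646 and -0.241. With a pseudocount of 48.8 they were 0.323, 0.763, 0.191 and -0.572, and UNPD minus UNSC with UNTD minus UNPD, which share arrays, was -0.728 (-0.601 without the dim filter). RAPD minus UNPD with UNTD minus UNPD was 0.476 without the dim filter and 0.545 with that pseudocount, within its error of 0.478. With a pseudocount of 3.05 the correlation of RAPD minus UNPD with UNTD minus UNSC was 0.117. None changed sign under these or under quantile normalization. Signal over background limits values near the dim-signal level.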

Other observations

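Of the tests in this part, those of a lower share of the main cell type, of an axis that separates replicates, of a swap with an UNTD array and of an untreated array labelled RATD replicate 1 were chosen after the results were seen, as was the 75th percentile covariate among the alternatives.

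Further gene lists and single genes were examined in the TD subset. Against UNSC, Irf7, a regulator of interferon genes, rose by 2.74 ± 0.38 log2 units in UNTD, and 3 of 34 interferon response genes rose and 0 fell, also over the list alone (camera adjusted p = 0.000634, adjusted p = 0.348 with an estimated correlation). Of 22 antigen presentation genes 4 rose and 0 fell (8 and 0 over the list alone), with the class II gene H2-Aa at 2.88 ± 0.58 (camera adjusted p = 0.00301, adjusted p = 0.319 with an estimated correlation). Fn1, which encodes fibronectin, was higher by 4.63 ± 0.33. The pro-apoptotic genes Bmf and Bcl2l11 were higher by 2.24 ± 0.29 and 1.51 ± 0.21, within an apoptosis list that was not called (median 0.04, adjusted p = 0.108). Notch1, Notch2 and the Notch effector gene Rbpj were higher by 1.14 ± 0.16, 1.32 ± 0.20 and 1.18 ± 0.22, within a Wnt and Notch list that was not called (median 0.23, adjusted p = 0.0859).

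The surrogate light chain genes Igll1 and Vpreb1, known from B cell precursors, stood at 12.10 and 9.83 in UNSC and were lower in UNTD (log2 difference -2.05 ± 0.21 and -2.83 ± 0.26), and in RAPD than in UNPD (-1.30 ± 0.21 and -2.50 ± 0.26), but the B cell list was not called in either comparison: 2 of 17 members were higher and 3 lower in UNTD (adjusted p = 0.867), with Cd22 higher by 2.18 ± 0.38, and 0 were higher and 2 lower in RAPD (adjusted p = 0.977). The glucose transporter gene Slc2a3 rose with ATRA by 4.02 ± 0.45 in PD, near its difference of 3.75 ± 0.45 in TD. In UNTD against UNPD, 3 of 17 primary granule genes rose and 10 fell (3 and 12 over the list alone, median -0.78, camera adjusted p = 0.0142, adjusted p = 0.518 with an estimated correlation), a call lost after quantile normalization (median -0.49, adjusted p = 0.384) and without UNTD replicate 2 (adjusted p = 0.0583). The homeobox A cluster, whose genes mark early progenitors, was called in none of the 7 contrasts, with a median of 0.27 in UNTD against UNSC (adjusted p = 0.862), nor were the stem and progenitor genes (-0.37, adjusted p = 0.102).

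UNPD lay apart from UNSC, with a median oxidative phosphorylation difference of 0.55, and none of the 4 technical explanations tested was argued against. That median was 0.196 after quantile normalization, and it lay at the 85.29th percentile of 10000 random lists matched on gene length and signal, so array scaling and a length dependence such as RNA quality gives may each contribute. RAPD replicate 2 minus replicate 1 correlated with UNPD minus UNSC at 0.867 across bright genes, but this was noticed first on the principal components. A weaker ATRA response in RAPD replicate 2 could also give it, and that array was nearer to the UNPD arrays (SD 0.582 and 0.529) than replicate 1 (0.868 and 0.735). On the second principal component, however, RAPD replicate 2 (25.6) lay farther from the UNPD arrays (-8.73 and -11.2) than replicate 1 (19.5). Cyp26a1 was similar on both (7.64 against 7.95 on replicate 1). The UNTD arrays showed no such axis (-0.056). The untreated UNPD arrays, which help to define the axis, did differ along it (-0.594), which ATRA cannot explain. Their difference also correlated at -0.5 among bright genes with that between the RAPD arrays, and these pairs share no array. Untreated replicates were thus separated along the axis in PD and not in TD, and the value of 0.867 alone does not decide its cause. With the 75th percentile as a covariate, which was added after the data were seen, 0 genes were called against 3766, as that explanation would give, but it cannot be told apart from the groups: they explain a share of 0.928 of the covariate, the median SE grew 2.73-fold, and called genes went from a median size of 1.07 (SE 0.244) to 0.341 (SE 0.539), with 52.5% keeping their sign. A biological difference between the sorted subsets stays open beside these.

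UNTD had far higher monocyte and dendritic genes than UNSC. A lower share of the main cell type, made up by marrow cells of many types, would raise markers that only those other types express. Among members above the dim-signal level on the 4 arrays, the median of 17 monocyte genes (3.16) exceeded that of 32 genes of the B cell, T and NK cell, erythroid, and eosinophil, basophil and mast cell lists (-0.17, or -0.16 for all 71 members) by 3.33 (95% interval 1.88 to 4.73, over genes that are not independent). The 32 genes had to pass that level in UNSC too, which leaves out genes that only added cells would bring. It keeps genes high in UNSC, such as Igll1 and Vpreb1, which a lower share of the main type would lower. All 71 members, without that limit, had no higher median. Those beyond the 32, however, lay at or under the level on at least an UNSC or UNTD array. The test therefore cannot decide on such a mixture, nor on an admixture of monocytes alone, which would give the same values. Resident macrophages in the sort would bring C1qa, C1qb and C1qc, whose median difference was 3.03 and met the value set beforehand, yet C1qb differed by -0.30 and none of them exceeded 5.90 on an UNTD array, where the dim-signal level reaches 5.12. Genes that near the floor decide nothing, so resident macrophages cannot be told apart here from leukaemic cells with monocytic expression, although per the labels the cells were sorted from GFP-marked leukaemia. A difference in maturation between the subsets stays open and was not tested.

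RATD replicate 1 lay nearer to the UNTD arrays than to RATD replicate 2. A swap with an UNTD array is argued against, since each UNTD array lay at least 2.22 times as far from RATD replicate 2 as from the other UNTD array. An untreated array under its label is argued against by Cyp26a1, which exceeded the highest of the 6 untreated arrays by 3.65 log2 units, more than the largest difference of 2.89 between untreated replicates. A weaker ATRA response in replicate 1 may explain the position, although Cyp26a1 was no lower on replicate 1 (9.07) than on replicate 2 (8.26). Along the ATRA difference of PD the slope of replicate 1 was -0.00916 against 0.426 for replicate 2, a ratio of -0.0215 (95% interval -0.0726 to 0.0201). These slopes are measured from the UNTD mean, so a position near UNTD by itself lowers them. The ATRA difference of PD itself averages 2 unlike RAPD arrays. The interval resamples genes of 1 array each, and genes are not independent replicates. SC-like cells in replicate 2 may also contribute, with a slope of 0.162 on UNSC minus UNTD beside 0.476 on the ATRA difference. Yet replicate 2 lay farther from the UNSC arrays (SD 0.694 and 0.699) than replicate 1 (0.521 and 0.524) over bright genes. Of all arrays, RATD replicate 2 lay nearest to RAPD replicate 1 (0.45), and the swap test did not cover RAPD arrays. The stated duration of 3 to 5 days leaves a difference in treatment open and untested.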
